A study of Vitis vinifera with 8 samples.

How the data were processed

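Transcripts in young leaves of Vitis vinifera cv. Sultana were measured on 8 one-colour (Cy3) Agilent arrays, 4 from plantlets infiltrated with the 35S:VvBHLH075 construct and 4 from plantlets infiltrated with the empty vector, as the labels group them. Per the labels' protocols, plantlets were grown at 25 °C with 16 h of light, 7 plants aged 6 weeks were infiltrated per bacterial suspension under vacuum (2 rounds of 2 min at 90 kPa), and RNA came from about 100 mg of leaf after 7 days of recovery. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.5.1.1, and the processed signal deposited by the authors is a linear intensity after background subtraction and spatial detrending on each array, with no normalization between arrays. The deposited value table equals that processed signal within a tolerance of 0.01 for 100% of probes, on a linear scale and without centring, with column medians from 103.58 to 246.73. The mean spot signal was not used here, so the normexp background correction took the median spot and median local background intensity of the deposited scanner files. No pooling of replicates is stated in the sources used here.

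The processed signal was log2 transformed and the 75th percentile of each array was subtracted. Control spots were left out, and 11 to 117 spots per array with outlier flags were set to missing. Each of the 34369 probes has its own locus ID. Probes well above background on at least 4 of the 8 arrays were tested, 26823 in all, of which 24010 were well above background on all 8. Median processed signals per array ranged from 103.507 to 245.021, and the 75th percentile in log2 units was 10.11 ± 0.27 (SD, n = 4) in controls and 10.54 ± 0.40 (SD, n = 4) in the overexpression group, with an exact permutation p of 0.171. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a probe was not well above background on any array of a group, its fold is given as at least the mean of the bright group over the mean, in the dim group, of the higher of the lowest well-measured signal of each array and the probe's own signal. No pair of arrays held identical values: the smallest median absolute log2 difference of any pair was 0.18.

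Neither the deposited files nor the RefSeq gene table pair the locus IDs with gene names or descriptions: 0 of the IDs matched the table. The locus of VvBHLH075 was set from prior knowledge of the grapevine gene models before the data were examined. The other loci are given as members of lists, whose locus IDs and ID ranges were also entered from prior knowledge and cannot be checked against a description here, so a range may hold other genes. No coordinates were used, and chromosomes are read from the locus IDs. Of 38 lists fixed before the data were examined, 31 rest on descriptions and could not be filled, among them all lists of markers of other cell types, which were therefore not analysed here. A further 8 lists were entered after the files were opened and before any comparison. In all, 15 lists were filled and 12 had at least 5 tested loci. Values of further single loci, named from prior knowledge after the files were opened, were computed and are not reported, since no source used here pairs those loci with names.

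The rule for named genes, set before the data were examined, took VvBHLH075, then the called genes with a described product, of which there were 0 because the files hold no descriptions, and then the 3 members with the smallest p of each list past camera, given here as ranges without IDs. VIT_05s0077g00500 and VIT_05s0049g00760 were chosen after their values were seen. Lists were tested with camera (preset correlation 0.01, repeated with an estimated one) and fry, and list means per array with two-sided exact permutation tests. Counts in lists are given adjusted over all genes and adjusted over the list alone. The interaction of group and slide was fitted in limma.

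The steps were tested on simulated data built from the overexpression and control arrays, with 26543 genes, 4 arrays per group, 200 changed genes and 5 runs. There 46.8% of genes changed by 1 on the log2 scale were called, and 83.6% of those changed by 2. The rates were 95.6% for a change of 3 and 98% for a change of 4, and 5.93% of called genes were false. A further set of 40 genes was shifted by 0.6. Noise was drawn independently for each gene, without slide effects or correlation between loci, so these rates may be too high for the real arrays. The rates also depend on the 200 planted genes, since more changed genes make the adjusted threshold easier to reach. In the real comparison only 2 genes were called. The alternatives tried were other scalings, normexp background correction with an offset of 50, the deposited value table as it stands, other filters on dim probes, replicate and slide blocks, a variance trend, array weights, stricter thresholds and leaving out each array. Keeping spots with outlier flags and leaving VvBHLH075 out of the ripening list were added after seeing the data. Single genes other than VvBHLH075 and lists are compared across settings relative to the median of all genes, which was decided after a first look at the alternatives.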

Results

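Leaves of grapevine plantlets (Vitis vinifera cv. Sultana) were profiled on 8 one-colour Agilent arrays after agroinfiltration, a method in which Agrobacterium carries a construct into plant cells for transient expression. In 4 samples the bacteria carried VvBHLH075, a gene for a basic helix-loop-helix transcription factor, under the constitutive 35S promoter, and in 4 control samples they carried the empty vector. Plantlets were 6 weeks old at infiltration and young leaves were taken after 7 days of recovery. The array held 34369 probes, each with its own locus ID, and 26823 of them were well above background on at least 4 of the 8 arrays and were tested. Between 25278 and 26977 probes were well above background on the control arrays and between 26808 and 27788 on the overexpression arrays. The group means were 25778 ± 807 (SD, n = 4) and 27345 ± 506 (SD, n = 4), with a two-sided exact permutation p of 0.0571. No spot was saturated. The number of arrays limits the precision of every value below. The labels number the plantlets of each group as lines without saying whether they came from separate infiltrations, so p-values measure the spread between these samples, which may be partly technical.

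The comparison asked which transcripts differ in leaves that overexpress VvBHLH075, in a series on the onset of berry ripening. The probe of the VvBHLH075 locus, VIT_17s0000g00430 on chromosome 17 by the numbering of its ID, was 6.05-fold higher in the overexpression group. Its normalized log2 signal was -1.16 ± 0.31 (SD, n = 4) in controls and 1.44 ± 0.31 (SD, n = 4) in overexpressing leaves, and all 4 overexpression arrays lay above all 4 controls (two-sided exact permutation p = 0.0286, the smallest possible). The log2 difference was 2.60 with a standard error of 0.20 and a limma adjusted p of 0.0208, and its unadjusted p, 7.75e-07, had rank 1 among the tested genes. The difference was 2.85 within the first slide and 2.34 within the second. With the slide as a block the adjusted p was 0.0731, and leaving out 1 array at a time gave log2 differences of 2.48 to 2.73 with adjusted p from 0.0341 to 0.190.

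**Figure D1:**
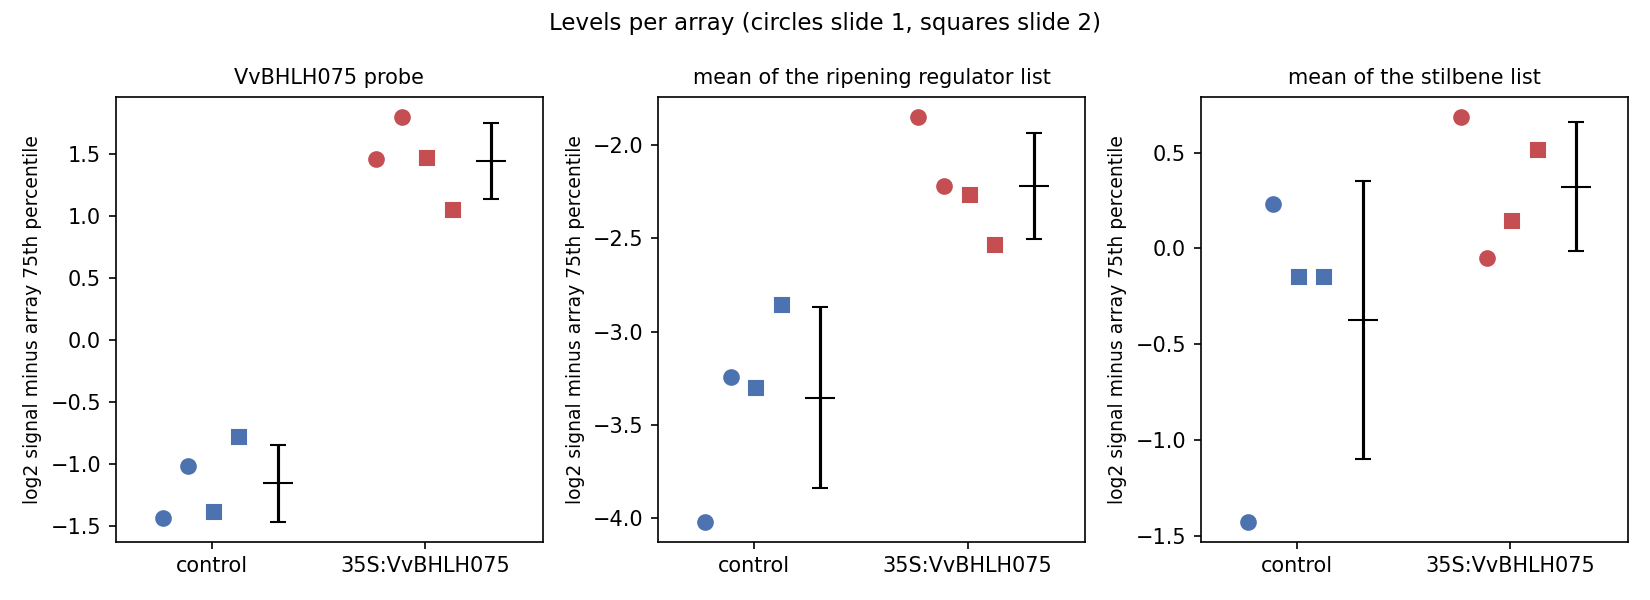
Normalized log2 signal per array (log2 processed signal minus the 75th percentile of the array) of the VvBHLH075 probe, of the mean of 6 ripening regulator loci, VvBHLH075 among them, and of the mean of the stilbene loci, each panel on its own axis range. Points are arrays, circles on slide 1 and squares on slide 2, and the black bars are mean and SD of the 4 arrays of a group; the VvBHLH075 probe lies between -1.43 and -0.79 in controls and between 1.04 and 1.80 in overexpressing leaves.

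Beyond the introduced gene, 1 other locus passed the test over all genes. VIT_05s0077g00500, singled out after its values were seen, was at least 2.83-fold higher in overexpressing leaves, where it was well above background on 4 of 4 arrays and on 0 of 4 control arrays. That detection pattern was shown by 95 probes and the reverse by 0, and detection is read from signals before scaling. VIT_05s0077g00500 had an adjusted p of 0.0492, and it passed in 4 of 13 other settings with all arrays and in 0 of the 8 fits that left out 1 array. Its control signals were not above background, so the bound holds for the reported setting only: the measured log2 difference relative to all genes, 2.41 there and itself no estimate of a fold, was 0.29 with normexp and quantile normalization and 0.47 with normexp and the 75th percentile. With limma, 2 genes were called higher and 0 lower at an adjusted p under 0.05, against 12 higher and 4 lower at an adjusted p under 0.10. At an unadjusted p under 0.05 there were 1827 higher and 1660 lower genes, 3487 in all, where 1341 would be reached by chance. That count was 1761 with normexp and the 75th percentile and 6131, of 34369 genes, with no filter on dim probes. The count of called genes was 0 with the slide as a block and 11 with arrays weighted by their quality. It was 333, of which 332 were higher, when the arrays were not scaled, a setting that shifts the median of all genes by 0.43 on the log2 scale.

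A list of 6 regulators of the transition to ripening in berries, VvBHLH075 among them, was higher as a group in overexpressing leaves by camera (adjusted p 2.18e-06 with the preset correlation of 0.01). With an estimated correlation the p was 0.0263 before and 0.316 after adjustment. All 6 members were measured higher, and 4 of them rose when adjusted over the list alone, against 1 when adjusted over all genes. The 3 besides VvBHLH075 rose by 0.64, 0.77 and 0.87 on the log2 scale (the 0.77 was 0.42 with normexp and quantile normalization), and the other 2 members measured 0.94 and 1.00 higher with unadjusted p of 0.131 and 0.115. The list mean was -3.36 ± 0.48 (SD, n = 4) in controls and -2.22 ± 0.28 (SD, n = 4) in overexpressing leaves, a 2.20-fold difference with a two-sided exact permutation p of 0.0286 (0.171 adjusted over the 12 lists). Without VvBHLH075, a choice made after seeing the data, 3 of 5 members rose when adjusted over the list alone, the mean log2 difference was 0.85, and camera gave p = 8.29e-05, or p = 0.0501 with an estimated correlation, and the fry adjusted p was 0.0884.

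The stilbene list covers loci entered for stilbene synthases, which make resveratrol in grapevine, and for their regulators. It was higher as a group by camera (adjusted p 1.11e-11), and with an estimated correlation the p was 0.200 before and 0.624 after adjustment. Of its 48 tested loci, 47 were measured higher. None was called over all genes or adjusted over the list alone, and 14 had an unadjusted p under 0.05, all higher. The mean log2 difference was 0.70, from -0.37 ± 0.73 (SD, n = 4) in controls to 0.32 ± 0.34 (SD, n = 4). The 3 loci with the smallest p were 0.78 to 1.06 higher. Relative to all genes, these loci measured 0.43 to 0.85 with normexp and the 75th percentile. The exact permutation p of the list mean was 0.0857. Control replicate 1 had the lowest list mean, -1.43, and without it the mean log2 difference, relative to all genes, was 0.35.

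The list of phenylpropanoid entry, a range of loci entered for phenylalanine ammonia-lyase, the first enzyme of the pathway, was higher by camera with an adjusted p of 0.0349, and with an estimated correlation the p was 0.408. Of its 22 tested loci 18 were measured higher, 1 of them with an unadjusted p under 0.05, and 0 were called over all genes or adjusted over the list alone. Their mean log2 difference was 0.20, and the 3 loci with the smallest p were 0.35 to 0.92 higher. With normexp and the 75th percentile, relative to all genes, the mean was 0.12 and these 3 loci measured 0.058 to 0.70. Without control replicate 1 the mean, relative to all genes, was 0.072 (adjusted p 0.410), and the call was also lost without overexpression replicate 1 (0.146) or 3 (0.0685) and with no filter on dim probes (0.0528). The flavonoid and anthocyanin list had 13 of 16 tested loci measured lower, with a mean log2 difference of -0.10, a camera adjusted p of 0.0671 and 0 loci with an unadjusted p under 0.05. It passed camera in 4 of the other settings with all arrays, the lowest mean being -0.35 (adjusted p 0.00588) with probes well above background on all 8 arrays. It passed in 3 of the 8 fits that left out 1 array, whose means ran from -0.27 without overexpression replicate 1 to 0.095 without replicate 4. Lists with fewer than 5 tested loci were not tested as groups. The NAC list held 2 loci that also belong to the ripening list, both of which rose when adjusted over the list alone. The 2 tested loci of the abscisic acid list measured -0.39 and -0.26, and the 3 of the expansin list measured -0.53, 0.24 and 1.21, with 0 of either called over all genes or adjusted over the list alone.

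**Figure D2:**
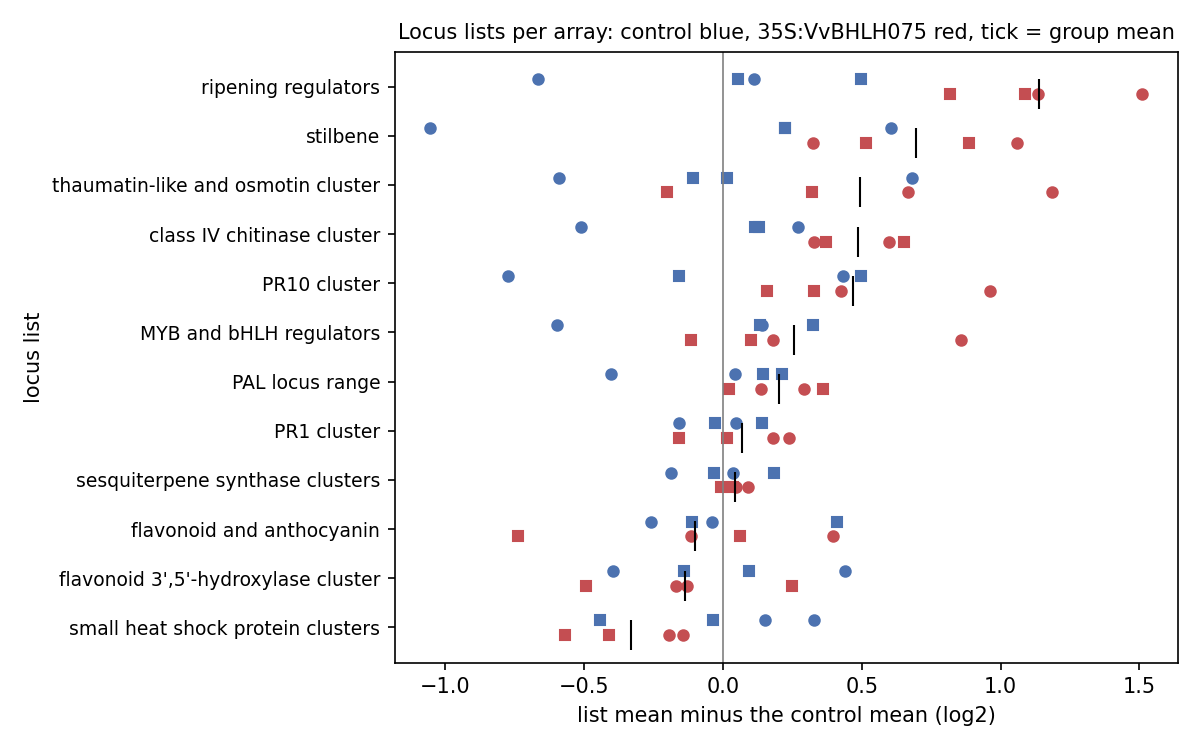
Mean normalized log2 signal of each of the 12 tested locus lists per array, minus the control mean of that list (x axis, log2). Blue points are control and red points overexpression arrays, circles on slide 1 and squares on slide 2, and the black tick is the overexpression mean. The ripening regulators, VvBHLH075 included, have the largest mean difference, 1.14 (0.85 without VvBHLH075), and the small heat shock protein clusters the lowest, -0.33.

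The 8 locus ranges and lists entered after the files were opened, and before any comparison, were meant to cover defence, secondary metabolism and heat shock genes. The class IV chitinase range was higher by camera (adjusted p 0.0125, and p = 0.141 with an estimated correlation), with 11 of 15 loci measured higher and 3 that rose when adjusted over the list alone, by 0.78 to 1.68. Its list mean was 1.40-fold higher, with an exact permutation p of 0.0286 (0.171 adjusted over the lists), and without control replicate 1 its mean log2 difference was 0.32 (camera adjusted p 0.143). With normexp its mean was 0.30 after quantile normalization and 0.25 with the 75th percentile, and the locus at 1.68 measured 0.66 and 0.65. In the same settings the locus at 0.78 measured 0.57 and 0.43, and the third, at 1.36, measured 1.38 and 1.18. The thaumatin-like and osmotin range was higher by camera (adjusted p 0.0125, and p = 0.251 with an estimated correlation), with 10 of 11 loci measured higher and 0 called adjusted over the list alone. Its 3 loci with the smallest p were 0.64 to 1.01 higher, and the lowest of them measured 0.42 with normexp and the 75th percentile and 0.37 without overexpression replicate 4. Its mean log2 difference of 0.49 was 0.30 without control replicate 1 (adjusted p 0.125), 0.25 without overexpression replicate 1 (0.146) and 0.74 without overexpression replicate 3. The small heat shock protein ranges were lower by camera (adjusted p 0.0125, and p = 0.260 with an estimated correlation). There 27 of 42 loci were measured lower, and 4 fell and 1 rose when adjusted over the list alone. The 3 with the smallest p measured -1.07, -0.74 and 0.83 (the first -0.67 with normexp and the 75th percentile). The call was lost without control replicate 1 (mean -0.22, adjusted p 0.0560) or overexpression replicate 3 (0.0510), with no filter on dim probes (0.102) and with normexp and the 75th percentile (0.0642). The PR10 range (mean log2 difference 0.47, camera adjusted p 0.0710), the PR1 range (0.07, 0.617) and the flavonoid 3',5'-hydroxylase range (-0.14, 0.304) did not pass. Among the other settings, PR10 passed in 6 with all arrays (adjusted p 0.0128 with quantile normalization) and in 3 that left out 1 array, and its mean was 0.22 without control replicate 1. The flavonoid 3',5'-hydroxylase range passed in 2 and 2, with a mean of -0.26 without control replicate 2 and 0.015 without control replicate 1. The sesquiterpene synthase ranges had a mean of 0.03 and a median of 0.02, while camera gave the direction as lower, with an adjusted p of 0.825. The MYB and bHLH regulators of flavonoid and stilbene synthesis had a mean of 0.26 and a median of 0.40, while camera gave the direction as lower, with an adjusted p of 0.947. Of these 10 tested regulators 1 rose and 1 fell when adjusted over the list alone.

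In all, 6 of the 12 tested lists passed camera, 5 higher and 1 lower, 0 passed with an estimated correlation, and 1, the ripening list, passed fry (adjusted p 0.0113), which tests whether the genes of a list move, on balance, one way. That fry call was lost without VvBHLH075 in the list. The mixed test of fry, for change in either direction, passed for 3 lists: the ripening regulators, the small heat shock protein ranges and the MYB and bHLH regulators. The lists overlap: the regulators share 2 tested loci with the ripening list, 3 with the flavonoid list and 2 with the stilbene list, and the ripening and flavonoid lists share 2. Neither fry test compares a list with other genes. Control replicate 1 stood apart from the other arrays on the first principal component (-81.8, the others -12.5 to 32.3, 27.5% of the variance). Without that array 2 lists passed camera, the ripening regulators, with VvBHLH075 in the list, and the stilbene list. The estimated correlation between the loci of a tested list ran from 0.016 to 0.75.

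The arrays lay on 2 slides, each with 2 control and 2 overexpression arrays. The group differences within the first and the second slide correlated with r = 0.26 across genes, which are not independent replicates. A group-by-slide interaction passed for 1 gene, VIT_05s0049g00760 on chromosome 5, chosen after its values were seen. The probe was well above background on 4 of 4 overexpression arrays and on 1 of 4 control arrays, which lay on the second slide. Within the first slide the overexpression signal was at least 139.7-fold higher, and within the second the measured log2 difference was -0.55. The fitted interaction, on measured signals that include controls below background, was -7.78 with a limma adjusted p of 0.00280. The fitted difference over both slides had an adjusted p of 0.438.

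**Figure D3:**
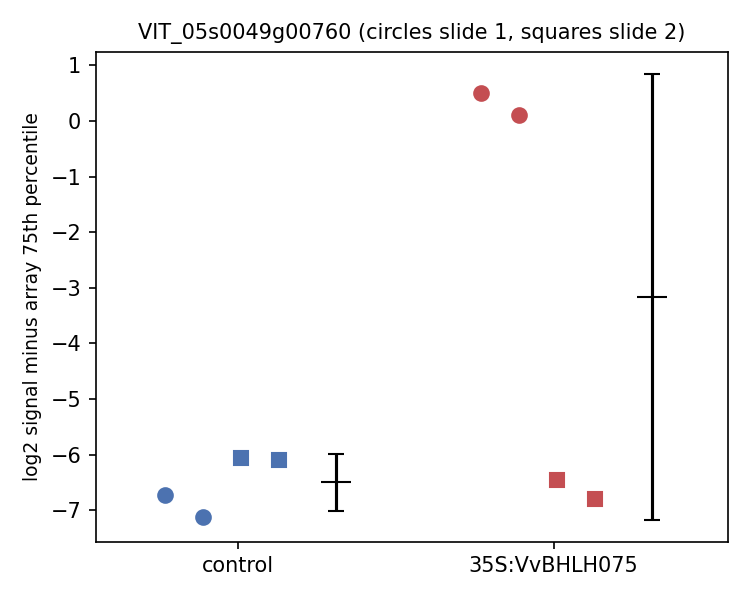
Normalized log2 signal of VIT_05s0049g00760 per array (log2 processed signal minus the 75th percentile of the array), with circles for slide 1, squares for slide 2, and black bars for mean and SD of the 4 arrays of a group. Overexpression replicates 1 and 2 lie at 0.50 and 0.12, and replicates 3 and 4, at -6.45 and -6.80, lie in the range of the controls.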

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

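The tests of the explanations for the split at VIT_05s0049g00760 were chosen after the result was seen. The first result that stood out is the number of probes well above background on control replicate 4, 26977, against 25278 to 25527 on the other 3 controls. This was the only sample far from the rest among 70 groups of values tested, and chance alone sets a sample apart in about 1 in 20 groups.

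The second is VIT_05s0049g00760, whose group difference differed between the slides by -7.78 on the log2 scale (limma interaction, adjusted p 0.00280): overexpression replicates 1 and 2 were high and replicates 3 and 4 were near the controls. The controls were -0.85 apart (slide 1 minus slide 2), but only 1 of 4 was well above background, so this does not settle whether the slide acted on the probe. A defect of a single spot is argued against, since the probe was high on 2 arrays and 2 other loci of the same ID block shared the split. Those 2 loci had replicates 1 and 2 over 2 log2 units above 3 and 4. In 1 of them, well above background on all 8 arrays, the controls were 0.12 apart between slides, in the other 2.37 the same way as the split. The tested locus before VIT_05s0049g00760 in the block measured 1.73, -3.74, -2.69 and -0.48 in replicates 1 to 4. The tested locus after it measured 0.55, -0.98, -4.54 and -1.02, all above the control mean of -5.95 (log2 difference 4.45, limma adjusted p 0.197). Some further loci of the block also measured higher in the overexpression group, for example by 2.85 and 4.22, while others were near 0 or lower. None of the block was called. The split with replicates 1 and 2 above 3 and 4 occurred in 42 tested genes and the opposite one in 2. Other pairings of the overexpression replicates gave at most 4. Those 4, with replicates 1 and 4 above 2 and 3, all lay in this same block. That pairing joins arrays of different slides, so the block also varied between replicates in a way that the slides do not follow. Pairings of the controls gave up to 24, and their pairing by slide, 1 and 2 against 3 and 4, gave 16 in each direction. In 22 of the 42 genes the controls were over 1 log2 unit higher on slide 1, so a slide effect may contribute to those. A difference between the plantlets or extractions stays open too, and no biological explanation was tested, since the labels do not separate these replicates.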

How the results depend on the processing

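The tests with outlier spots kept and without VvBHLH075 in its list were chosen after the data were seen. The number of called genes, 2 in the reported setting (2 higher, 0 lower), was 0 with the replicate block, the slide block, normexp with the 75th percentile or an adjusted p under 0.01. It was 1, a higher gene, with median centring, quantile normalization, no filter on dim probes, probes well above background on all 8 arrays, a test against a fold of 1.2 (treat), or outlier spots kept. It was 12 (8 higher, 4 lower) with normexp and quantile normalization, 11 (8 higher, 3 lower) with array weights, 333 (332 higher, 1 lower) without scaling and 285 (284 higher, 1 lower) with the deposited values. The last 2 settings leave the brightness of the arrays in, with a median shift of all genes of 0.43, and normexp with the 75th percentile shifts it by 0.15; for the others the cause was not tested. Leaving out 1 array at a time gave 0 to 2 called genes, 0 to 1 higher and 0 to 1 lower. The unadjusted count was 1761 with normexp and the 75th percentile, 6131 with no filter, 5045 without scaling, and 2478 to 3798 with 1 array left out.

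VvBHLH075 stayed higher in every setting. It was 2.60 higher on the log2 scale with the replicate block (adjusted p 0.279) and with the slide block (adjusted p 0.0731), which use up degrees of freedom, and 2.57 higher with normexp and the 75th percentile (adjusted p 0.184, cause not tested). The other settings with all arrays passed the threshold. With 1 array left out it was 2.48 to 2.73 higher (adjusted p 0.0341 to 0.190), and 3 of the 8 fits passed. The labels do not say whether the replicate numbers pair the samples. Little sign of pairing was seen: the same-number correlations of deviations ran from -0.16 to 0.30, and 2 of 8 arrays correlated best with their own number. With so few arrays this cannot settle the question.

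Of the 12 lists, 6 passed camera in the reported setting, 0 with an estimated correlation, 1 with fry, and 2 to 8 with 1 array left out, the 2 being without control replicate 1. The stilbene and ripening lists passed camera with the preset correlation in every setting in which they were tested (array weights and the variance trend do not enter camera). The ripening list held VvBHLH075 in all of them. Without that gene it was tested in the reported setting only, so these passes do not show that its other members moved. With probes well above background on all 8 arrays the ripening list had too few loci. Mean log2 differences, relative to all genes, changed sign for 4 lists that had not passed: flavonoid and anthocyanin (-0.27 to 0.095 with 1 array left out, above 0 without control replicate 4 or overexpression replicate 4), sesquiterpene synthase (-0.053 with normexp and the 75th percentile, -0.019 with no filter, -0.021 with array weights, and -0.023 to 0.076 with 1 array left out, below 0 without control replicate 1), flavonoid 3',5'-hydroxylase (-0.26 to 0.015 with 1 array left out, above 0 without control replicate 1) and the MYB and bHLH regulators (-0.069 with probes well above background on all 8 arrays). The cause was not tested. Of 679 values of lists and of single genes other than VvBHLH075 under alternatives, 612 kept direction and side of the threshold. A further 28 lost and 31 gained the call, and 8 changed sign. Of these genes only VIT_05s0077g00500 was called in the reported setting, and it kept its call in 4 settings and lost it in 17. For the other genes, keeping the side of the threshold meant staying uncalled. Not run were the mean of several probes per gene (there is 1 probe per ID), the slide as a random block (slides hold both groups) and a scan day block (there was 1 day). Dim probes are limited by their signal over background. Of 10 equal bins by brightness, the dimmest had a median log2 difference of 0.20 (exact permutation p 0.2 between the groups) and the brightest -0.13, with bins between falling in order, and the cause was not tested.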

Other observations

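The tests of the gene counts and of the stilbene list were chosen after the results were seen, while those of the list count and of adjacent loci were set before. Detection differed in 1 direction: 95 probes were well above background on all 4 overexpression arrays and on no control array, and 0 showed the reverse. Detection is read from unscaled signals, and the 75th percentile of the overexpression arrays was 0.43 higher on the log2 scale (exact permutation p 0.171). Loci with IDs starting XLOC were tested less often than the predicted genes with VIT IDs, 2228 of 4392 (50.7%) against 24512 of 29798 (82.3%), and 11.5% and 13.1% of those tested had an unadjusted p under 0.05.

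Many genes differed between the groups at an unadjusted p under 0.05 without passing adjustment over all genes. The 2 called genes were equalled or exceeded in 3 of the 35 splits of the arrays, the real one included, so chance cannot be excluded for that count. The highest other count, 24, came from the split by slide, which points to a slide structure. With the slide as a block 0 genes were called, but the VvBHLH075 difference stayed at 2.60 and the block uses up degrees of freedom. The loss of calls therefore does not show that the slide made the 2 called genes. The 3487 genes at an unadjusted p under 0.05 were reached only by the real split (1 of 35, highest other 2549), which argues against chance. Quantile normalization left 3330 genes (highest other split there 2850), which argues against brightness differences between arrays as the whole cause. With normexp the count was 3630 after quantile normalization (highest other split 3210). It was 1761 with normexp and the 75th percentile (highest other split 1496), nearer to the 1341 reached by chance, so its size depends on the processing. The 3080 genes left without control replicate 1 argue against that array alone as the cause. The 3616 genes with the slide as a block say nothing about a slide difference, since each slide held 2 arrays of each group. A broad response to the overexpression is one hypothesis, and a difference in RNA or labelling between the groups, whose numbers of probes above background gave an exact permutation p of 0.0571, could not be separated from it and may add to the count.

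The rise of the stilbene list may rest on shared signal or shared regulation of near-identical loci: its camera adjusted p of 1.11e-11 assumes nearly independent loci, and with the estimated correlation of 0.75 the p was 0.200. The number of lists past camera, 6, was reached in 7 of the 35 splits, the highest other count being 7, so chance cannot be excluded for that count either. What stays open is whether the overexpression moved these loci, since the exact permutation p of the list mean was 0.0857.

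A further hypothesis, that adjacent loci respond together to the overexpression, did not meet the prediction set for it. The log2 differences of 22216 pairs of adjacent tested loci correlated with r = 0.153 across genes, far above the highest of 1000 shuffled orders, 0.019. However, 3 of the 35 splits, the real one included, gave a correlation as high, up to 0.166. The other splits that reached it kept most of the controls together and so share part of the real contrast, and the test cannot exclude the hypothesis. The lowest correlation of any split was 0.066, so adjacent loci vary together whichever way the arrays are grouped.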
